A study of Mus musculus with 8 samples.

How the data were processed

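RNA from mouse striatum at postnatal day 30 was profiled on Illumina mouse bead arrays, with 4 arrays labelled wild-type and 4 labelled PGC-1α null. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, frozen tissue was extracted with Trizol and biotin-labelled cRNA was hybridised. GenomeStudio is the tool named in the submitters' processing notes, without a version.

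Per the file headers, the deposited table gives a mean bead intensity and a detection p-value for each probe on each array. Its values are linear, were not normalized between arrays and held no negative values, and its rows are named by probe and gene symbol. The deposited p-values for detection set each probe against the negative controls of its own array; the control probes themselves were not used here. The authors' processed intensity values for the same probes are linear, with a median per array of 14.9 to 15.0, a minimum of -18.4 and a maximum of 36977.3 on each of the 8 arrays. About 23.1% of them lie below 0. These features fit a background subtraction and a quantile normalization, but the authors' method is not given in the sources used here. The processed columns ranked the probes as the raw column of the same array did (Spearman's rho of 1 on each array, against at most 0.936 with any other array). Only raw values entered the main test, and the processed values served as an alternative. For that alternative, processed values under 16, a floor above the median of each array, were set to 16 before log2. No column of per-sample values was left unused.

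The raw intensities were corrected and normalized with neqc in limma 3.58.1 under R 4.3.3. This step estimates background from the detection p-values, adds an offset of 16, normalizes quantiles between arrays and takes log2. A probe was kept when its detection p was under 0.05 on at least 4 of the 8 arrays, whatever their group. That left 13413 of 25697 probes (52.2%), standing for 10008 of 18138 gene symbols. Gene symbols are those of the array's design; where the RefSeq gene table lists a newer symbol, it is given once.

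Each probe was fitted with lmFit and eBayes as null minus wild-type, two-sided, with Benjamini-Hochberg adjustment over all kept probes and a threshold of 0.05. Differences are on the log2 scale with the standard error (SE) of the fit. Gene lists were tested with camera in limma, with a preset correlation of 0.01 between genes, on 1 probe per gene (the kept probe with the highest mean). The adjustment covered 47 lists of pathways, cell types and PGC-1α targets with at least 5 measured genes. The lists were written from general knowledge of the tissue before the data were examined, as were the tests and the alternatives, except where stated. Of 872 list genes, 802 were matched to the table, 24 of them through a synonym that is no other gene's own symbol, and 662 were tested; the others are not analysed here. Camera with an estimated correlation and fry, which asks whether a list's genes move one way on balance, were run beside it. A list score is the mean over its genes of each array's log2 value minus the gene's mean over the 8 arrays.

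The rule for naming genes took, of genes past the threshold without overlap between the groups, the 12 with the largest difference in each direction. Where fewer than 6 passed, it took the 10 genes with the smallest p in that direction, which are then said not to pass. It added Ppargc1a, up to 4 genes with the smallest p from each list past the threshold, up to 3 from other lists described, each sex-linked gene and chromosome 5 neighbour past the threshold, and genes with probes called in opposite directions. Genes with placeholder symbols were left out. Genes named outside the rule are said to have been chosen after their values were seen. Where a probe was not detected on any array of 1 group, only a bound is given: the brighter group's mean against the dimmer group's mean of, per array, the higher of the probe's own value and the lowest value among detected probes.

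The steps were tested on simulated data before use. With 200 of 13413 probes changed, the fit recovered 23.3% of changes of 1.5-fold, 96.9% of changes of 2-fold and 100% of changes of 4-fold. The simulated noise was independent between probes and had variances already moderated by the fit, so recovery in the real data may be lower. Of the real probes, 21 differed by 1 or more on the log2 scale and 0 passed, so changes of 2-fold are not excluded. In simulated arrays with independent genes and no effect, camera called 0 of 47 lists on average over 20 draws; real genes are correlated, so this says nothing of correlated lists. The number of arrays limits the precision: the median SE of a log2 difference was 0.15 and its 95% interval reached a median of 0.32 to either side.

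The alternatives were the replicate number as a block, no background correction, cyclic loess, median centring, the authors' processed values, no detection filter, a filter of detection p under 0.01 on all 8 arrays, an offset of 50, an eBayes prior with trend and robust fitting, array weights, averaged probes, each array left out in turn, removal of sex-linked genes and chromosome 5 neighbours of Ppargc1a, a fold of at least 1.5, both other list tests, and lists without shared members. A covariate for the level of the Y-linked gene Eif2s3y and one for the score of the cortical list were chosen after seeing the data.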

Results

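Gene expression was measured in striatum of mice labelled as lacking PGC-1α, the coactivator encoded by Ppargc1a that drives genes of mitochondrial metabolism, and of wild-type mice of the same age, postnatal day 30. Each group had 4 arrays. The comparison asks which striatal transcripts depend on PGC-1α. The labels name medium spiny neurons, the main projection neurons of the striatum, as the cell type, but the source is striatal tissue, so the values cover every cell type in it. The series title speaks of a deletion in these neurons and the sample labels of null mice; which kind of deletion these arrays represent is not settled by the sources used here. The mean raw intensity per array ran from 295 to 499, and 13009 to 13910 probes were detected. The labels do not say that replicates are separate animals, so p-values measure the spread between these samples, which may be technical in part. All 8 arrays lay on 1 chip, with the wild-type group in the first 4 positions and the null group in the last 4, so position on the chip and group cannot be told apart.

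The probe of the deleted gene gave similar levels in both groups. It was detected on all 8 arrays and averaged 7.57 (log2) in wild-type and 7.69 in null arrays, a difference of 0.12 (SE 0.23, limma adjusted p = 0.94, n = 4 per group) with a 95% interval from -0.38 to 0.61. The 4 wild-type arrays read 7.31, 7.18, 7.86 and 7.94, and the 4 null arrays 7.26, 8.05, 8.06 and 7.39. Leaving out 1 array moved the difference to between -0.02 (without wild-type replicate 2) and 0.26 (without null replicate 1). The part of the gene that was deleted is not given in the sources used here, and a probe outside that part checks nothing, so this value neither bears out nor contradicts the labels. The groups are therefore named below as the arrays are labelled, and each direction rests on those labels. The related coactivator gene Ppargc1b differed by -0.22 (SE 0.14) and Nrf1, which encodes a transcription factor for respiratory genes, by -0.20 (SE 0.14); the list of 12 measured PGC-1 family and partner genes was not past the threshold (median -0.08, adjusted p = 0.46). The 11 measured genes known from the literature to respond to PGC-1α in neurons went both ways: 6 were higher and 5 lower in null arrays, with a median of 0.07 (camera adjusted p = 0.88). Among them, Cycs (cytochrome c) differed by 0.23 (SE 0.14), Idh3a, a subunit of a citric acid cycle enzyme, by -0.23 (SE 0.16) and Sod2, the mitochondrial superoxide dismutase, by 0.10 (SE 0.15).

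**Figure D1:**
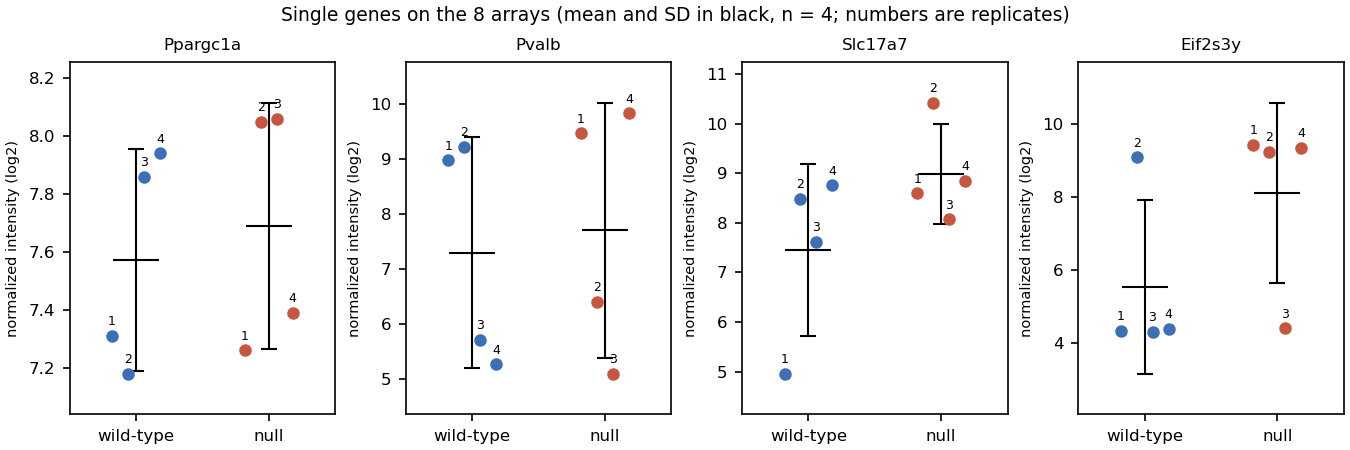
Normalized log2 intensity of 4 genes on each array, by labelled group; points are arrays marked with their replicate number, and black lines give the mean and SD (n = 4). Ppargc1a and Pvalb each have high and low arrays in both groups; Slc17a7, a cortical neuron gene, is highest in null replicate 2 (10.42) and lowest in wild-type replicate 1 (4.96), and Eif2s3y, a Y-linked gene, is high on 1 wild-type and 3 null arrays.

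No single gene passed the threshold. With limma, 0 genes were higher and 0 lower in arrays labelled null, and the smallest adjusted p was 0.63; 408 genes were higher and 469 lower at an unadjusted p under 0.05, where 928 probes stood against 670.7 by chance. The groups did not overlap for 555 probes (4.14%; chance gives 2.86%). Only 21 probes differed by 1 or more on the log2 scale. The genes with the smallest p are therefore given as values that did not pass. Those lower in null arrays included 2 potassium channel genes, Kcna5 at -0.87 (SE 0.16) and Kcnk6 at -0.64 (SE 0.13), and the neurokinin receptor gene Tacr3 at -0.56 (SE 0.11). Scg2 (secretogranin II) differed by -0.69 (SE 0.14), Vgf by -0.63 (SE 0.14), and Hap1, which encodes a partner of huntingtin, by -0.68 (SE 0.15), Pqbp1 by -0.58 (SE 0.13), Dbpht2 by -0.69 (SE 0.14), Cpne5 by -0.70 (SE 0.16) and Otof by -0.61 (SE 0.14). Those higher in null arrays included Ctsk (cathepsin K) at 0.61 (SE 0.12), Zfp238 (now Zbtb18), a neuronal transcriptional repressor, at 0.65 (SE 0.13), Gpx4, a glutathione peroxidase, at 0.51 (SE 0.13), Usmg5 (now Atp5md), a small subunit of ATP synthase, at 0.54 (SE 0.13), the glutaminase gene Gls2 at 0.47 (SE 0.11), Zfp62 at 0.65 (SE 0.16), Ccdc3 at 0.71 (SE 0.18) and the Y-linked Ddx3y at 0.87 (SE 0.22). Sex-linked genes described below had the Y-linked pattern on 3 null arrays and 1 wild-type array, so the Ddx3y difference cannot be told apart from sex. For 14 probes 1 group was undetected on all its arrays; of these, Thbs3 was at least 1.27-fold and Elavl4 at least 1.37-fold brighter in null arrays, and Dlk1 at least 1.22-fold brighter in wild-type arrays (adjusted p of 0.63, 0.67 and 0.67).

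Gene lists gave a different count. With the preset correlation, 16 of 47 lists passed, 7 higher and 9 lower in null arrays. With an estimated correlation 0 passed (lowest adjusted p = 0.59, 1 list at an unadjusted p under 0.05), and with fry 0 passed (lowest adjusted p = 0.44, 3 lists at an unadjusted p under 0.05). The mixed form of fry, which asks whether genes move in any direction, passed 1 list, p53 and apoptosis genes (adjusted p = 0.0494), which did not pass with camera. The estimated correlations between members of the 16 lists had a median of 0.24, well above the preset value. Of the 35 ways to part the 8 arrays 4 against 4, 7 gave at least as many lists as the labels did, up to 22. Over the 47 lists, 12 members passed when adjusted over the list alone, and 0 over all genes.

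The list with the smallest p held genes of cholinergic interneurons, the acetylcholine-releasing cells of the striatum. All 10 measured genes were lower in null arrays, with a median of -0.48 (camera adjusted p = 6.57e-08; adjusted p = 0.59 with an estimated correlation). The list score was 0.23 ± 0.15 (SD, n = 4) in wild-type and -0.23 ± 0.28 in null arrays, without overlap (exact permutation p = 0.0286, the smallest that 4 against 4 can give). None of the 10 genes passed over all genes, and 5 passed when adjusted over the list alone: Tacr3, the transporter gene Slc10a4 at -0.66 (SE 0.17), the peptidase gene Ecel1 at -0.62 (SE 0.16), the transcription factor gene Lhx8 at -0.45 (SE 0.17) and Chat, which encodes choline acetyltransferase and was named after its value was seen, at -0.55. The score was lowest in null replicate 2 (-0.65). Without that array the median was -0.37 and the list stayed past the threshold. For the scores of the other lists past the threshold the exact permutation p ran from 0.0857 (direct-pathway and GABA) to 0.6 (myelinating oligodendrocytes). The score of antioxidant defence genes, a list not past the threshold (camera adjusted p = 0.0568), also parted the groups without overlap. It was higher in null arrays, with the same exact permutation p of 0.0286 and 12 of 19 genes higher (median 0.07). These permutation p-values were not adjusted for the number of lists scored.

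Genes of medium spiny neurons were lower in null arrays as well. Of 16 measured genes shared by these neurons 14 were lower, with a median of -0.29 (camera adjusted p = 0.000317, or 0.59 with an estimated correlation). The score of this list overlapped between the groups (exact permutation p = 0.171). Ppp1r1b, which encodes DARPP-32, differed by -0.42 (SE 0.14), Rgs14 by -0.57 (SE 0.14), Pde1b by -0.33 (SE 0.14) and Arpp21 by -0.33 (SE 0.15); 0 passed over all genes and 1, Rgs14, when adjusted over the list alone. In the list of direct-pathway neurons 8 of 10 genes were lower, with a median of -0.24 (adjusted p = 0.00498; adjusted p = 0.59 with an estimated correlation). The prodynorphin gene Pdyn differed by -0.80 (SE 0.20), and it and Dlk1 passed when adjusted over the list alone. Genes reported to be lost in Huntington disease striatum were lower in 14 of 16 cases, with a median of -0.22 (adjusted p = 0.00191; adjusted p = 0.67 with an estimated correlation), Ngef among them at -0.30 (SE 0.13). This list shares 6 measured genes with the shared medium spiny list, Ppp1r1b and Arpp21 among them, and did not pass with lists without shared members (adjusted p = 0.0773). Genes of indirect-pathway neurons did not pass (median -0.23, adjusted p = 0.25). Genes of GABA synthesis, transport and receptors had a median of -0.14 with 11 of 14 lower (adjusted p = 0.0325; adjusted p = 0.59 with an estimated correlation), with Slc32a1, the vesicular GABA transporter, at -0.51 (SE 0.14), which passed over the list alone, and Gad1 at -0.38 (SE 0.16). Without null replicate 2 the medians were -0.16 for the shared genes (adjusted p = 0.0468), -0.11 for the direct pathway (0.0468) and -0.08 for the Huntington list, which no longer passed (adjusted p = 0.36), while that of the GABA list stayed at -0.13. The GABA list was lost without wild-type replicate 1 (adjusted p = 0.0818), wild-type replicate 2 (0.0507), wild-type replicate 3 (0.095), null replicate 1 (0.101) or null replicate 4 (0.115), and its median was -0.21 without wild-type replicate 4.

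**Figure D2:**
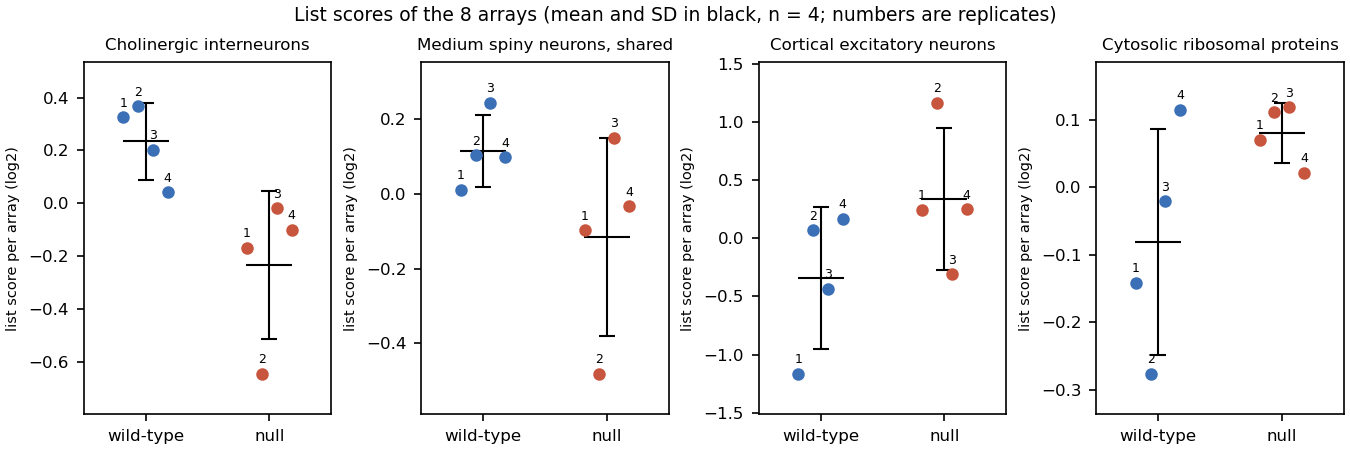
List score of each array (mean log2 deviation of the list's genes from their mean over all arrays), by labelled group; points are arrays marked with their replicate number, and black lines give the mean and SD (n = 4). Cholinergic scores do not overlap between the groups, and null replicate 2 has both the lowest medium spiny neuron score (-0.48) and the highest cortical score (1.17).

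Genes of cortical neurons were higher in null arrays, and those of other neurons outside the striatum were not. All 9 measured genes of cortical excitatory neurons were higher, with a median of 0.50 (camera adjusted p = 0.00186; adjusted p = 0.59 with an estimated correlation). Slc17a7, the vesicular glutamate transporter of cortical neurons, differed by 1.53 (SE 0.72), Nrn1 by 1.67 (SE 0.62) and Tbr1 by 1.05 (SE 0.51), and 0 of the 9 passed over all genes or over the list alone. The cortical score ran from -1.16 in wild-type replicate 1 to 1.17 in null replicate 2, where the shared medium spiny neuron score was -0.48. Without null replicate 2 the cortical median was 0.16 and did not pass (adjusted p = 0.0634), and without wild-type replicate 1 it was 0.32. Genes of pallidal, septal and thalamic neurons had a median of -0.18 with 7 of 10 lower and did not pass (adjusted p = 0.14). With the cortical score as a covariate, chosen after seeing the data, the shared medium spiny, direct-pathway, Huntington and GABA lists no longer passed. Their medians were -0.14, -0.05, -0.06 and -0.11 (adjusted p of 0.16, 0.24, 0.52 and 0.24), so that of the GABA list stayed near its -0.14, while the cholinergic list did (median -0.33, adjusted p = 0.00218). The astrocyte (0.08, adjusted p = 0.26), oligodendrocyte (0.22, 0.0571), immediate early (-0.26, 0.46) and mural (-0.20, 0.0621) lists described below no longer passed either. Nor did the cortical list (median -0.04, camera adjusted p = 0.935), which was fixed in advance, as its own score was the covariate. This left 7 of the 16 lists past the threshold.

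Genes of oligodendrocytes and astrocytes were higher and vascular genes lower in null arrays, and each call was lost without at least 1 single array. Myelinating oligodendrocyte genes were higher in null arrays in 15 of 15 cases, with a median of 0.21 (camera adjusted p = 0.00859; adjusted p = 0.72 with an estimated correlation), with Cnp at 0.48 (SE 0.20) and Mobp at 0.57 (SE 0.31). Without wild-type replicate 3, whose score was -0.98, the median turned to -0.04 (adjusted p = 0.77); it was 0.12 without null replicate 1 (adjusted p = 0.10) and 0.36, 0.34 and 0.34 without wild-type replicate 1, wild-type replicate 2 and wild-type replicate 4. Astrocyte genes had a median of 0.14 with 13 of 15 higher (adjusted p = 0.0229; adjusted p = 0.59 with an estimated correlation), with Gfap at 0.54 (SE 0.22) and the glutamine synthetase gene Glul at 0.27 (SE 0.13). That list was lost without wild-type replicate 3 (adjusted p = 0.095), null replicate 1 (0.0826), null replicate 2 (0.062) or null replicate 4 (0.0533). Endothelial genes were lower in 12 of 13 cases, with a median of -0.15 (adjusted p = 0.0167; adjusted p = 0.59 with an estimated correlation), with the growth factor receptor gene Flt1 at -0.50 (SE 0.15) and Itm2a at -0.36 (SE 0.14). It was lost without wild-type replicate 3 (adjusted p = 0.0983), null replicate 1 (0.0816) or null replicate 3 (0.129), and its median was -0.09 without null replicate 3 and -0.25 without null replicate 4. Mural and fibroblast genes had a median of -0.19 with 10 of 11 lower (adjusted p = 0.0487; adjusted p = 0.59 with an estimated correlation), with Acta2 at -0.42 (SE 0.15). This list was lost without wild-type replicate 1 (adjusted p = 0.0818), wild-type replicate 2 (0.166), wild-type replicate 3 (0.095), null replicate 1 (0.0816) or null replicate 3 (0.203), and its median was -0.10 without wild-type replicate 2 and -0.11 without null replicate 3. Microglial genes did not pass (median -0.02, adjusted p = 0.98).

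Parvalbumin interneuron genes and activity-regulated genes were lower by the preset test. The 8 measured interneuron genes had a median of -0.16 with 5 lower (adjusted p = 0.0317, or 0.59 with an estimated correlation), led by Gpr83 at -0.71 (SE 0.19), which passed over the list alone. The list score overlapped between the groups (exact permutation p = 0.486). It was 0.30, 0.50, -0.23 and -0.27 on the wild-type and 0.22, -0.31, -0.43 and 0.22 on the null arrays, so each group held high and low arrays. The list was lost without wild-type replicate 1 (adjusted p = 0.0528), wild-type replicate 2 (0.208), null replicate 2 (0.0537) or null replicate 3 (0.114), with medians of -0.10 without wild-type replicate 2 and -0.24 without null replicate 4. Pvalb itself, named after its values were seen, ran from 5.26 to 9.22 in wild-type and from 5.09 to 9.83 in null arrays (difference 0.41, SE 1.13, adjusted p = 0.95). Immediate early genes had a median of -0.44 with 10 of 13 lower (adjusted p = 0.0229, or 0.59 with an estimated correlation). Their list score gave an exact permutation p of 0.371. Dusp1 differed by -0.56 (SE 0.24) and Fosb by -0.48 (SE 0.17), while Nr4a2 stood at 1.25 (SE 0.47). The list was lost without wild-type replicate 1 (adjusted p = 0.213), wild-type replicate 4 (0.248), null replicate 2 (0.11) or null replicate 4 (0.0729), and its median was -0.26 without wild-type replicate 1.

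**Figure D3:**
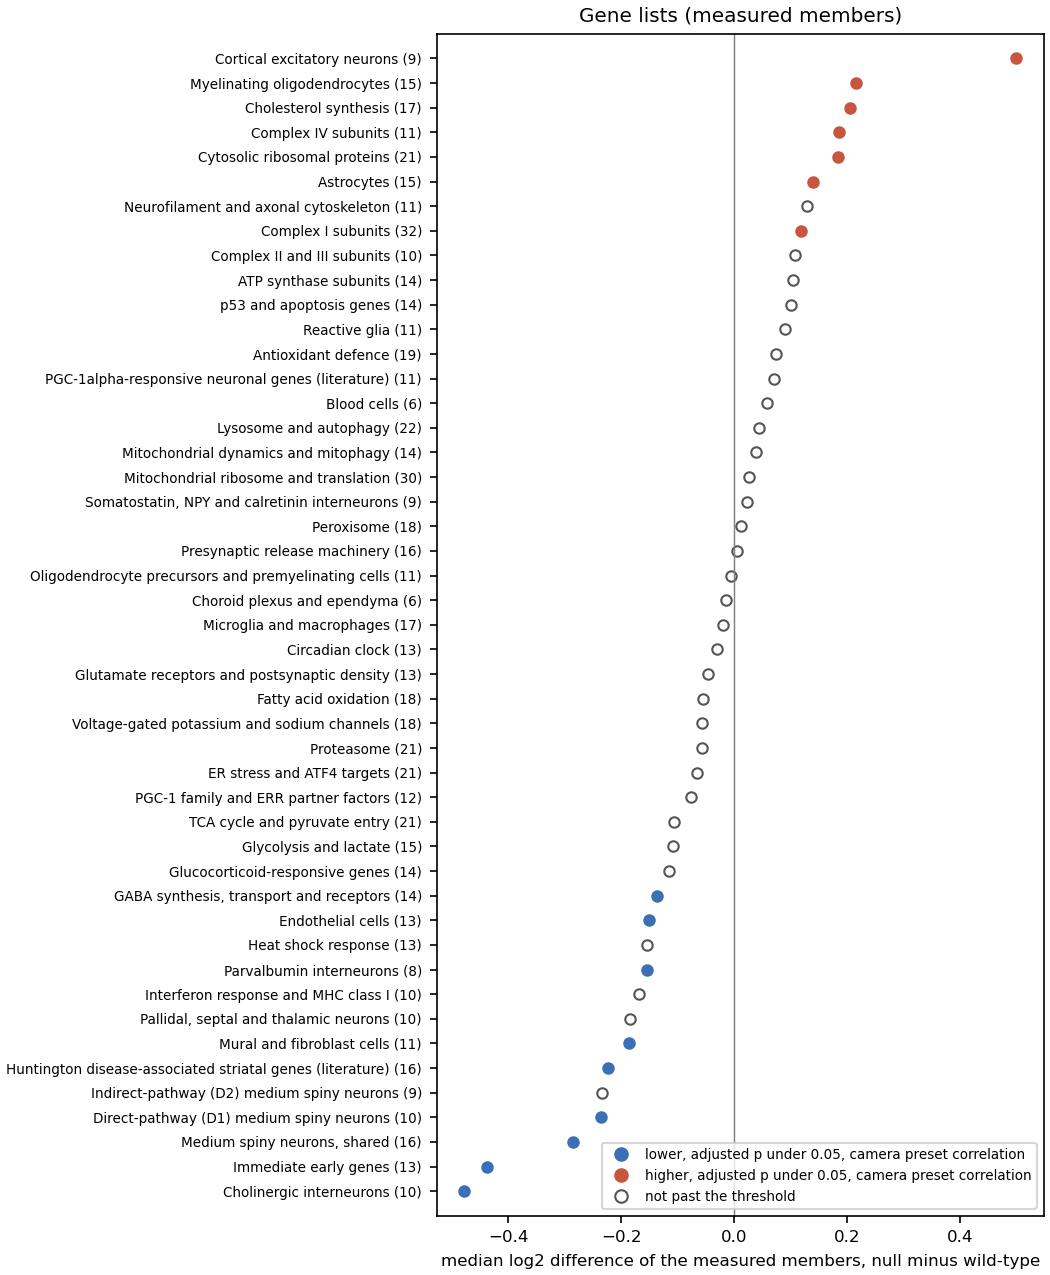
Median log2 difference, null minus wild-type, over the measured members of each of the 47 gene lists, with the number of members in parentheses. Filled points are the 16 lists past the threshold with the preset correlation, of which 0 passed with an estimated correlation; open points did not pass.

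Several lists of the translation and respiratory machinery were higher in null arrays. Of 21 cytosolic ribosomal protein genes 18 were higher, with a median of 0.18 (camera adjusted p = 0.000271; adjusted p = 0.59 with an estimated correlation), with Rps14 at 0.27 (SE 0.11) and Rps3 at 0.32 (SE 0.15). Complex I subunits had a median of 0.12 with 23 of 32 higher (adjusted p = 0.00225; adjusted p = 0.59 with an estimated correlation), Ndufa6 at 0.38 (SE 0.15) and Ndufb2 at 0.29 (SE 0.13) among them. Complex IV subunits had a median of 0.19 with 10 of 11 higher (adjusted p = 0.00498; adjusted p = 0.59 with an estimated correlation), with Cox7a2l at 0.30 (SE 0.13) and Cox6c at 0.25 (SE 0.12). No member of these 3 lists passed over all genes or over the list alone. Complex I was lost without wild-type replicate 4 (adjusted p = 0.0782), the ribosomal median was 0.09 without wild-type replicate 2, and the complex IV median was 0.11 without null replicate 1. Other mitochondrial lists did not pass. ATP synthase subunits had a median of 0.10 (adjusted p = 0.0922; Atp5j2 at 0.31, SE 0.12), complexes II and III 0.11 (adjusted p = 0.13; Uqcrh at 0.29, SE 0.11), citric acid cycle genes -0.11 (adjusted p = 0.0762; Fh1 at -0.24, SE 0.12) and fatty acid oxidation genes -0.06 (adjusted p = 0.61; Acadl at -0.36, SE 0.15). The citric acid cycle and fatty acid oxidation scores parted the arrays across the labels, as described below.

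Genes of cholesterol synthesis were higher in null arrays in 17 of 17 cases, with a median of 0.20 (camera adjusted p = 0.000271; adjusted p = 0.59 with an estimated correlation). Cyp51 differed by 0.49 (SE 0.17), Sc4mol (now Msmo1) by 0.47 (SE 0.18) and Sqle, which encodes squalene epoxidase, by 0.43 (SE 0.18); 0 passed over all genes or over the list alone. The median was 0.11 without wild-type replicate 3. The score was highest in null replicate 2 (0.29) and lowest in wild-type replicate 3 (-0.35). With the level of Eif2s3y as a covariate, chosen after seeing the data, the list no longer passed (median 0.11, adjusted p = 0.18). With the cortical score as a covariate its median was 0.13 and it passed (camera adjusted p = 0.0428).

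Sex-linked genes parted the arrays in a way that the labels, which do not give sex, leave open. The first Xist probe, for a transcript of the inactive X chromosome, read 8.22, 8.66 and 8.48 in wild-type replicates 1, 3 and 4 and 8.53 in null replicate 3, and 4.58 to 4.90 on the other arrays. The Y-linked Eif2s3y was at 9.10 in wild-type replicate 2 and at 9.25 to 9.44 in null replicates 1, 2 and 4, and at 4.32 to 4.41 on the other arrays. Both patterns thus occurred in each group, so neither group came from 1 animal. The probe of Ddx3y, also Y-linked, read 9.60, 9.95, 10.55 and 10.57 on the arrays with low Eif2s3y and 10.48 to 11.20 on the others. Its signal was thus not confined to arrays with the Y-linked pattern. With the Eif2s3y level as a covariate 6 of the 16 lists passed, among them the cholinergic (adjusted p = 7.13e-05), ribosomal (2.67e-06) and complex I (0.0178) lists, and so did 2 lists that had not passed without it, citric acid cycle (median -0.19, adjusted p = 0.00224) and glycolysis (-0.25, 0.00443). These calls use the preset correlation; without the covariate the estimated correlations of these 2 lists were 0.364 and 0.491, and adjusted p = 0.73 and 0.77 with an estimated correlation. The other 10 no longer passed: the GABA (median -0.15, adjusted p = 0.21), astrocyte (0.10, 0.36), complex IV (0.13, 0.13), shared medium spiny neuron (-0.18, 0.14), immediate early (-0.27, 0.36), oligodendrocyte (0.08, 0.61), cortical (0.18, 0.35), direct-pathway (-0.08, 0.22), Huntington (-0.11, 0.21) and cholesterol lists. The GABA median was no smaller than without the covariate. Of 35 listed neighbours of Ppargc1a on chromosome 5, 19 were measured; 0 passed over all genes and 1, Sepsecs, when adjusted over the list alone (0.0484), at least 1.08-fold brighter in wild-type arrays and undetected in null arrays.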

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

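The splits and the tests of the 3 patterns below were chosen only after the results were seen. Single arrays stood apart for some named genes: the gap to the nearest other array of its group as a share of the group's range exceeded Dixon's 95% critical value in 19 of 178 groups, where chance gives 1 in 20, or 8.9. These groups are not independent, so the excess over chance is not a result in itself. The sex-linked flags follow from 3 arrays with 1 pattern against 1 with the other in each group. Mobp is also a member of the flagged myelinating oligodendrocyte list. Null replicate 3 was low for Elavl4 (4.96), Ddx3y (10.57) and Gfap (5.83). Null replicate 2 stood apart for Vgf (9.10), Sqle (9.98) and Gad1 (11.36), and null replicate 4 for Rps3 (12.25) and Ttr (13.07). Wild-type replicate 1 was low for Cpne5 (5.34, the others 5.79 to 5.83). Wild-type replicate 3 stood apart for Cyp51 (7.73), Mobp (10.36), the myelinating oligodendrocyte score (-0.98) and the astrocyte score (-0.20). Sex-linked genes set apart wild-type replicate 2, with Eif2s3y at 9.10 and the Xist probes at 4.90 and 4.35, and null replicate 3, with Eif2s3y at 4.41 and the Xist probes at 8.53 and 8.30.

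The 8 arrays can be parted 4 against 4 in 35 ways, the labels being 1 of them. The labels had 0 genes past the threshold, which all 35 splits reach in advance, so this count tests nothing; 31 splits had 0 and the highest other had 9. At an unadjusted p under 0.05, 6 of 35 splits had as many genes (877, highest other 1252). For lists past the threshold 7 of 35 did (16, highest other 22). Chance cannot be excluded for these counts.

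Cholinergic interneuron genes were lower in arrays labelled null. Chance cannot be excluded, since 4 of 35 splits had a list, whichever it was, with as small a camera p (1.4e-09, smallest other 1.31e-15). The score difference, -0.47 (95% interval -0.855 to -0.0794), was -0.28 (-0.633 to 0.0708; list adjusted p = 0.00218) with the cortical score as a covariate, so cortical tissue may account for part of it. It was not reduced much by the Eif2s3y level (-0.44, interval -0.958 to 0.081; list adjusted p = 7.13e-05) or at all by the score of a ventral striatal list (-0.51, -1.16 to 0.139; 0.000528); these intervals reach 0 because they widened, so the tests neither bear out nor exclude sex or a more ventral dissection of the wild-type samples. Position on the chip and an effect of PGC-1α on these cells or their transcripts stay open as well.

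Complex I and complex IV genes were higher in arrays labelled null. Both medians lay at or above percentile 99.9 of 10000 random lists matched for mean expression. The percentile cannot decide on a shift of all bright probes. Quantile normalization had already given every array the same distribution of values, so such a shift was removed before the test. Members of a random list are unrelated, while those of the complex I and complex IV lists had estimated correlations of 0.23 and 0.21. The percentile is thus no test against chance either. With the Eif2s3y level as a covariate the score difference was 0.11 for complex I (95% interval -0.0785 to 0.289; 0.10, -0.0339 to 0.238, without it), with the list past the threshold (adjusted p = 0.0178), and 0.11 for complex IV (-0.197 to 0.412; 0.17, -0.0765 to 0.422, without it), with the list not past it (adjusted p = 0.126). As all these intervals include 0, the test decides nothing on unequal numbers of males and females. Chance (exact permutation p of 0.143 and 0.171 for the scores), the split across the labels below, position on the chip and an effect of PGC-1α stay open. The complex IV scores followed that split without overlap, though narrowly. They were 0.09, -0.0403, 0.21 and 0.22 on wild-type replicates 1 and 2 and null replicates 1 and 4. On wild-type replicates 3 and 4 and null replicates 2 and 3 they were -0.21, -0.18, -0.0408 and -0.0450. They overlapped between the labelled groups, and complex I scores overlapped across the split.

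PGC-1α-responsive genes parted the arrays across the labels. Of the 35 splits, the one with the most genes past the threshold set wild-type replicate 1, wild-type replicate 2, null replicate 1 and null replicate 4 against the other 4 arrays, and it stood at rank 1 of 35 by the responsive genes not called in any split (absolute value of their mean t 2.59, next split 1.26), while the labels stood at rank 27. A swap of labels between 2 wild-type and 2 null arrays could give this, but that rank raised the idea and so decides nothing. Ppargc1a also stood at rank 1 of 35 in this split, but went the opposite way. It was higher on all 4 other arrays (7.86, 7.94, 8.05 and 8.06) than on the first (7.31, 7.18, 7.26 and 7.39). The responsive list's score was high on the first 4 (0.27, 0.40, 0.33 and 0.46) and low on the others (-0.33, -0.46, -0.275 and -0.41). The fatty acid oxidation score, examined after the split was seen, parted likewise (0.13, 0.16, 0.16 and 0.08 against -0.10, -0.11, -0.20 and -0.12). The citric acid cycle score did so narrowly (-0.0036 in null replicate 4, -0.0091 in wild-type replicate 3). Its list shares Idh3a with the responsive list. Scores of complex I, complexes II and III and ATP synthase overlapped. A swap was to be borne out only if Ppargc1a went the same way as the responsive list, which it did not. This decides nothing either, as the Ppargc1a probe may lie outside the deleted part. More white matter in 4 of the dissections stays open too, as the split was also at rank 1 of 35 by myelinating oligodendrocyte genes (2.32, next split 2.14). Their score was lowest in wild-type replicate 3 (-0.98). It was close in wild-type replicate 1 (0.15) and wild-type replicate 4 (0.11), where the responsive list's score was 0.27 and -0.46. White matter by this score thus does not account for the gap between those arrays. Tissue from the pallidum, septum or thalamus in 4 of the dissections stays open as well, with the split at rank 5 of 35 by such markers. Their score overlapped across the split, with 0.37, 0.23, -0.0018 and -0.20 on the first 4 arrays and -0.18, -0.036, 0.034 and -0.21 on the others. Null replicate 4, at -0.20, had the highest score of the responsive list. A chromosome 5 segment carried along with the deleted gene also stays open, at rank 15 of 35. No array was moved to another group.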

How the results depend on the processing

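The covariate alternatives were chosen only after the results were seen. No alternative brought a gene past the threshold in either direction: the smallest adjusted p ran from 0.0516 (without null replicate 4) to 0.9995, and the genes at an unadjusted p under 0.05 from 369 with median centring to 1537 with no detection filter. Of 1453 values for genes named by the rule other than Ppargc1a, 0 passed and 4 turned direction. The count of lists past the threshold was 0 for camera with an estimated correlation and 0 for fry, 8 with the Eif2s3y level as a covariate and 9 with the cortical gene score as a covariate, against 16; of these 6 and 7 were among the 16, and 2 each were not (citric acid cycle and glycolysis, then glycolysis at an adjusted p of 0.0247 and interferon response at 0.00218). The Ppargc1a difference was -0.0153 without wild-type replicate 2, -0.00404 without null replicate 2, -0.00833 without null replicate 3 and 0.26 without null replicate 1, and 0.39, the highest of 21 alternatives, with the Eif2s3y level as a covariate. Sod2 was at -0.00298 without wild-type replicate 4 and at 0.22 without wild-type replicate 1. With the Eif2s3y level as a covariate the Xist probes were at 0.0322 and 0.447, and with the cortical gene score as a covariate Tbr1 was at -0.0432. Xist was high where Eif2s3y was low, and Tbr1 is part of the cortical score. These turns thus follow from the covariates and say little of how stable those genes are. The median of the myelinating oligodendrocyte list was -0.0388 without wild-type replicate 3 and 0.36 without wild-type replicate 1. The cholinergic and ribosomal lists passed in 22 of 24 alternatives, all but the other list tests. The cholinergic median ran from -0.616 with the authors' processed values, set to at least 16, to -0.173 with no background correction. The mural list passed in 9 of 24. It was lost with no background correction (median -0.056, adjusted p = 0.0729), median centring (-0.20, 0.107), offset 50 (-0.107, 0.0582), eBayes trend and robust (0.0577) and probes of a gene averaged (0.0522), and, like the astrocyte and Huntington lists, with lists without shared members and Ppargc1a (0.0773 each). The immediate early list was lost with no detection filter (-0.131, 0.0953) and array weights (-0.335, 0.119), the parvalbumin list with no detection filter (-0.0703, 0.0537), array weights (-0.139, 0.0747) and detection p under 0.01 on all arrays (-0.155, 0.0702), and the direct-pathway list with the last of these (-0.149, 0.0717). Of 31 lists not past the threshold, 11 passed in some alternative and 18 turned direction in some. The causes were not tested. Signal over background limits the comparison to the 13413 probes detected on at least 4 arrays.

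The labels share replicate numbers between the groups, but the deviations of arrays with the same number had correlations of 0.0881, -0.00368, 0.236 and 0.0454, of which only that of replicate 3 was over 0.1, so the numbers were not taken as pairs. With the replicate block 13 lists and 0 genes passed; the immediate early (adjusted p = 0.0827), parvalbumin (0.0539) and mural (0.0811) lists did not.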

Other observations

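The tests of the lists in this part and its genes were chosen only after the results were seen. A list of ventral striatal and basal forebrain genes, 13 of 17 measured, was lower in arrays labelled null in 12 cases, with a median of -0.50 (camera adjusted p = 1.91e-06 over 2 lists; adjusted p = 0.0805 with an estimated correlation; exact permutation p = 0.0571). Adjusted over the list alone 2 genes passed, Wfs1 at -1.13 and Cartpt at -1.22, and 0 over all genes. A list of neuropeptide and secretory granule genes had 10 of 14 members lower and a median of -0.10 (adjusted p = 0.0161; adjusted p = 0.11 with an estimated correlation). It holds Scg2, Vgf and Pdyn, whose values prompted it and which alone passed over the list, so its p restates those values.

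Some genes had a high and a low level within each group. Pvalb read 8.98, 9.22, 5.71 and 5.26 on the wild-type and 9.47, 6.40, 5.09 and 9.83 on the null arrays, and Pdk4, a kinase that restrains pyruvate oxidation, read 6.39, 6.08, 4.66 and 4.80, then 6.09, 5.12, 4.81 and 5.80. Neither passed between the groups by the fit (adjusted p = 0.95 and 0.99).

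The median, the mean and the test differed in sign for 6 lists, none of them past the threshold (adjusted p of 0.93 to 0.94): mitochondrial ribosome, circadian clock, glutamate receptors, peroxisome, oligodendrocyte precursors, and somatostatin, NPY and calretinin interneurons.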
